A study of Mus musculus with 6 samples.

How the data were processed

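RNA from mouse cochleae was measured on 1-colour Agilent arrays, with 3 wild-type and 3 Fabp7 knockout samples. Per the labels' protocols, all mice were females aged 7 months, and each sample pooled 4 cochleae of 2 mice, with the bony otic capsule kept and the vestibular organs removed. Each group therefore stands for 12 cochleae of 6 mice. The group was taken from the genotype given for each sample, and the replicate number from the sample titles.

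Per the labels, the RNA carried Cy3 dye, and the submitters' processing notes name Agilent Feature Extraction 10.7. For each array the authors deposited 1 raw signal intensity per probe, on a linear scale with no scaling between arrays, and each value was above 0. Which signal column was exported and how the background was treated is not given in the sources used here, and the tables used hold no control spots and no detection or saturation marks. The authors also deposited a matrix of log2 values. Each of its columns equalled the log2 raw signal of the same array minus a constant, to within 1e-05, and its 75th percentile lay between 0.00549 and 0.00803. The column medians of that matrix were −3.58, −3.67 and −3.67 in wild type and −3.55, −3.69 and −3.68 in knockout. All columns were matched to a sample.

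The log2 of the raw signal minus the 75th percentile of its array was computed here for 55676 probes. Gene names came from the platform's annotation table, in which 30625 probes had 1 gene, 25051 had none and 0 had several. Of the named probes, 30331 were found by gene ID in the RefSeq table of GRCm38.p6, which was used only for names and for which genes lie near each other, since no build is named with the arrays. A probe was kept when its signal exceeded the 40th percentile of its array on at least 3 of the 6 arrays, whichever the group, the rule set for tables without detection marks. Of the probes, 33484 passed. For a gene with several passing probes, the probe with the highest mean over all arrays stood for the gene, and probes without a name were kept as features of their own. This left 27189 features, 16143 of them named genes and 11046 unnamed probes.

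Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, no covariates), and p-values were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. Every log2 change is knockout minus wild type, given with the standard error of the fit, and a fold is 2 raised to it. Fabp7 was examined first, to check the labels. Other named genes followed a rule: 12 places in each direction for genes past the threshold with no overlap between the groups, filled, where fewer passed, by the lowest unadjusted p among genes with an absolute log2 change of at least 0.5. For each gene list described, up to 4 members were named, those with the lowest unadjusted p, and Npas2 and Arntl were added to the clock list after their values were seen. A total of 33 gene lists for cochlear cell types, cells of neighbouring tissues and pathways were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, with Fabp7 left out. Camera with an estimated correlation and limma's fry stand beside it. With an estimated correlation, camera also takes its degrees of freedom from the arrays instead of the genes, which by itself raises its p-values. Called genes within 20 Mb of Fabp7 were set against those among all other named genes with Fisher's exact test, two-sided. The same test at an unadjusted p under 0.05 was added after 0 genes had been called. Apart from these additions, the groups, gene lists, tests described here, naming rule and a list of other settings were fixed before the data were examined.

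The fit was tested on simulated data of the same 27189 features. Of 50 features changed by 0.5 on the log2 scale, 18% were recovered, against 72% at 1, 92% at 2 and 100% at 4, with 4 calls among the unchanged features. The noise was normal with the spreads that the fit had already drawn towards a common value, so they differed less between features than real ones. The 50 features of each size were changed together. Many true changes ease the adjusted threshold, so these shares overstate the recovery of a single changed gene, and the evened spreads may add to this. In a second simulation the cartilage list, shifted by −0.5, had a camera adjusted p of 9.53e-28, and 1 other list was called. Its members were drawn independently there, whereas on the real arrays their estimated correlation was 0.302. That simulation therefore cannot show how camera behaves on correlated members. Alternatives covered the scaling, the source of the values, the filter, the probes of a gene, the model of the spread, the replicate number as a block, the thresholds, and each array left out in turn, with the filter and the choice of probe repeated on the other arrays. Background correction with normexp and a block for slide or scan date were planned and not run, because the columns they need were not among those used here. With 1 value per probe and no background estimate, the number of arrays limits the precision, and the fold of a gene near the lowest signals depends on how low signals are treated.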

Results

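Gene expression was profiled in the cochleae of adult female mice with and without Fabp7, a brain-type fatty acid binding protein that carries long-chain fatty acids inside glia and other cells. The 6 samples were 3 wild-type and 3 Fabp7 knockout pools, each of 4 cochleae from 2 mice aged 7 months, so that tissue of the organ of Corti, the lateral wall, the ganglion and the surrounding bone was measured together. The 75th percentile of the raw signal ranged from 581.06 to 677 across the arrays, and the 10 brightest probes held between 2.68% and 3.00% of the signal. Pairs of arrays correlated across the 27189 features tested at 0.988 to 0.994. Wild-type array 1 stood apart at the dim end, with a 25th percentile of 6.66 against 3.92 to 4.69 on the others.

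The first question was whether the targeted transcript was lost. Fabp7 gave raw signals of 2674, 1554 and 1860 in wild type and of 10.9, 3.75 and 3.43 in knockout. Its wild-type signals lay at percentiles 87.0, 82.6 and 84.1 of their arrays, and its knockout signals at percentiles 33.0, 23.7 and 15.9. The scaled log2 signal was 1.56 ± 0.39 (SD, n = 3) in wild type and −6.86 ± 0.92 (SD, n = 3) in knockout, a difference of −8.42 ± 0.47 (SE), or 343-fold. Its 95% interval ran from −9.58 to −7.26. All 6 labels agreed in direction with this single probe. The limma adjusted p over all features was 0.0610, above the threshold, although it was the lowest of any feature. With knockout array 1 left out, the difference was −8.95 with an adjusted p of 0.00733, and over the alternatives tried the adjusted p ranged from 0.00108 to 0.486. With signals under the 40th percentile raised to it, the fold was 95.2.

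**Figure D1:**
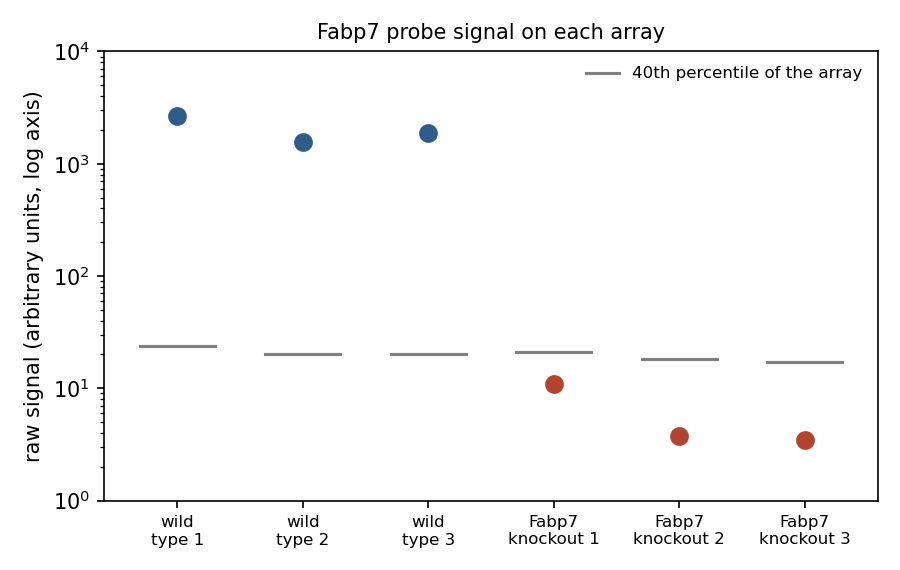
Raw signal of the Fabp7 probe on each of the 6 arrays, on a log axis in arbitrary units, with wild type in blue, knockout in red and a grey bar at the 40th percentile of each array. The wild-type points sit between 1554 and 2674, and the knockout points, from 3.43 to 10.9, all lie under the 40th percentile of their arrays.

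Beyond Fabp7, the comparison asked which cochlear transcripts differ without it. Among the 12 genes at the head of the higher side, none of which passed the adjusted threshold, were a pair of core clock repressors, Per2 (log2 change 0.74 ± 0.12, SE) and Per3 (0.84 ± 0.17). Insig1, which holds back sterol synthesis by retaining the SREBP escort protein, differed by 0.57 ± 0.08. Transporters were Slc5a2, a sodium-glucose cotransporter, at 1.25 ± 0.23 and Slc4a10, a sodium bicarbonate transporter, at 0.83 ± 0.16. The Slc4a10 signal on wild-type array 3 lay just under the 40th percentile. Muscle-associated members were Dupd1, a dual-specificity phosphatase, at 0.87 ± 0.07 and Tmod4, a tropomodulin that caps actin filaments in skeletal muscle, at 0.58 ± 0.12. Tmod4 was brightest on knockout array 2 (raw signal 662 against 492 and 534), the array that also held the highest score of the skeletal muscle list, 2.21. Cpne7, a calcium-dependent phospholipid-binding copine, differed by 0.51 ± 0.08, and Corin, the protease that activates natriuretic peptide, by 0.53 ± 0.09. Tmem163, a zinc transporter, was at 1.11 ± 0.23, but all 3 of its wild-type signals lay under the 40th percentile of their arrays, and with signals raised to that percentile it was at 0.50. The other two places went to the uncharacterised genes Gm6729 (0.66 ± 0.11) and A530016L24Rik (0.70 ± 0.14, and −0.30 by its other probe past the filter). In each of these genes all 3 knockout arrays lay above all 3 wild-type arrays. After Fabp7, Dupd1 had the lowest adjusted p among them, 0.190 by limma.

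The 12 genes at the head of the lower side likewise did not pass. They included Slco1b2, an organic anion transporter, at −0.93 ± 0.08 (limma adjusted p = 0.193), and Hkdc1, a hexokinase family member, at −0.80 ± 0.11. Kera, a small leucine-rich proteoglycan of collagenous matrix, was at −1.48 ± 0.22, and at −1.07 with signals under the 40th percentile raised to it (its signals on knockout arrays 1 and 2 lay at percentiles 33.1 and 37.7, and on array 3 just above that level). Serpina3n, a serine protease inhibitor induced in inflammation, was at −0.92 ± 0.14, with its signal on knockout array 3 just under the 40th percentile. A pair of secreted signals, the Wnt potentiator Rspo2 (−0.52 ± 0.08) and the BMP ligand Gdf6 (−0.55 ± 0.09), stood beside Igsf5, an immunoglobulin-family adhesion protein, at −0.57 ± 0.09 (−0.37 by its other probe, of nearly equal signal). For the remaining genes the probes of a gene disagreed. Trpm1, a melanocyte channel, was at −0.67 ± 0.09 by its brightest probe, while its other probes past the filter gave 1.34 and 0.92. Gab3 was at −0.85 ± 0.13 against −0.09 by its other probe, Rhox8 at −0.95 ± 0.15 against 0.01, Pnma2 at −0.74 ± 0.11 against −0.01, and Pdss2, which makes the coenzyme Q side chain, at −0.67 ± 0.10 against 0.10.

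Over all 27189 features, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1550 features, 827 higher and 723 lower, where 1359.45 would come by chance. Of the 16143 named genes 774 reached that level, under the share that chance gives, so the excess lay among unnamed probes. A fit on named genes alone gave 499 higher and 413 lower, together above that share. Among all features, which direction held more depended on the scaling, with 692 higher and 824 lower after quantile normalization and 719 and 779 after scaling to the median of tested features. With wild-type array 1 left out, 1314 features were higher and 801 lower at that level, and with array weights 2125 and 1302. The weights were 2.69 for knockout array 2 and 2.24 for wild-type array 3, against 0.41 to 0.89 on the others. Every result with array weights therefore leans on those arrays. Without wild-type array 2, limma called 2 features higher after adjustment, Gdpd3 and an unnamed probe, and without wild-type array 3 it called 1 higher, an unnamed probe. Without knockout array 1 it called 1 lower, Fabp7. Gdpd3, singled out after its values were seen, was at 2.43 ± 0.98 over all arrays with an adjusted p of 0.866. Over the 16143 named genes alone, adjustment left 1 gene, Fabp7 (limma adjusted p = 0.0362), with the next at 0.113. The median half-width of the 95% interval of a change was 0.28 on the log2 scale, a 1.21-fold change, and 96.2% of features had an estimated change under 0.5. The groups did not overlap in 12.4% of features, where chance gives 10%.

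Of the 33 gene lists, camera called 11 with its preset correlation, 9 lower and 2 higher in knockout relative to other genes. Cartilage genes were lower as a list, with 12 of 14 measured members below 0 and a mean change of −0.15. Matn1, a matrilin of cartilage matrix, was at −0.69 ± 0.14, the proteoglycan Epyc at −0.41 ± 0.10 and the matrix protein Chad at −0.31 ± 0.09, whereas aggrecan (Acan) was at 0.43 ± 0.08. These 4 passed when adjusted over the list alone, and 0 members passed over all genes. The list had a camera adjusted p of 0.000717 and an adjusted p of 0.694 with an estimated correlation. Its mean was −0.09 both without knockout array 1 (camera adjusted p = 0.0351) and with array weights (0.0201), and the list score of wild-type array 3 (−0.02) lay below that of knockout array 3 (0.02). Adipocyte genes were also lower, with 9 of 12 members below 0, a mean of −0.40 and a median of −0.19. Pck1, the gluconeogenic and glyceroneogenic carboxykinase, was at −2.45 ± 0.46, and the lipid droplet proteins Plin1 and Cidec at −0.81 ± 0.26 and −0.73 ± 0.23, with the lipase Lipe at −0.49 ± 0.17. Pck1 alone passed when adjusted over the list alone, and 0 passed over all genes (camera adjusted p = 0.000717, and adjusted p = 0.371 with an estimated correlation). Its signal exceeded the 40th percentile on 5 of 6 arrays. With that level passed on all 6 the adipocyte mean was −0.27 (camera adjusted p = 0.0014). Other lipid and retinoid binding proteins had 5 of 8 members below 0 and a mean of −0.40. The plasma retinol carrier Rbp4 was at −0.32 ± 0.07 and Rbp7 at −0.65 ± 0.16, both past the threshold when adjusted over the list alone, against 0 over all genes. The liver-type Fabp1 was at −2.17 ± 0.90 and the cellular retinoic acid binding protein Crabp1 at 0.26 ± 0.16 (camera adjusted p = 0.0121, and adjusted p = 0.371 with an estimated correlation). With the 40th percentile passed on all 6 arrays, which leaves out the dim Fabp1, the mean of this list was −0.15 (camera adjusted p = 0.0358). No single array decided the calls of these 3 lists. With an estimated correlation 0 lists were called, and fry called 0 in one direction, with 5 lists at an unadjusted p under 0.05. The mixed test of fry, for members that differ in either direction, called 4 lists, those of cartilage, lipid and retinoid binding proteins, the stria vascularis and cholesterol synthesis (adjusted p = 0.00582, 0.00939, 0.00956 and 0.00956). In the cholesterol synthesis list only 1 member, Insig1, named above, was at an unadjusted p under 0.05 by limma, and the median change was 0.03. With wild-type array 1 left out, camera called 20 lists, and with array weights 17.

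Macrophage genes lay below 0 in 14 of 15 members, with a mean of −0.11, and the complement genes C1qa and C1qb were at −0.26 ± 0.08 and −0.26 ± 0.13, beside Cx3cr1 at −0.18 ± 0.06 and Ms4a7 at −0.23 ± 0.10 (camera adjusted p = 0.000717, and adjusted p = 0.694 with an estimated correlation). Interferon-response genes lay below 0 in 20 of 22 members, among them Ifi27l2a at −0.75 ± 0.23, Isg15 at −0.48 ± 0.16 and the transcription factor Irf7 at −0.72 ± 0.27 (camera adjusted p = 0.00214, and adjusted p = 0.849 with an estimated correlation). Their list scores, the mean centred log2 signals of the members, were −0.12, 0.50 and −0.21 in wild type and −0.03, 0.20 and −0.34 in knockout. Genes of osteoblasts and osteocytes had 14 of 16 members below 0, with the matrix proteoglycan Omd at −0.17 ± 0.10 and the Wnt inhibitor Sost at −0.44 ± 0.25, while alkaline phosphatase (Alpl), the member with the lowest unadjusted p, was at 0.17 ± 0.08 (camera adjusted p = 0.00871, and adjusted p = 0.809 with an estimated correlation). Without wild-type array 2 the mean was −0.04 for macrophages (camera adjusted p = 0.0688) and −0.02 for bone cells (0.552), and the mean of the interferon list turned to 0.11 (adjusted p = 0.408). Without knockout array 3 the interferon mean was 0.03 (adjusted p = 0.483), and with array weights 0.08 (adjusted p = 0.573). Without wild-type array 1 the means were −0.19 for macrophages (camera adjusted p = 1.68e-07) and −0.19 for bone cells (1.12e-05), against −0.11 and −0.13 over all arrays. The macrophage mean was −0.05 with no filter on dim probes (adjusted p = 0.0211).

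Vessel genes had 13 of 18 members below 0, with the angiopoietin receptor Tek at −0.28 ± 0.08 and Pecam1 at −0.22 ± 0.09 (camera adjusted p = 0.00989, and adjusted p = 0.371 with an estimated correlation). Their call ended without wild-type array 1 (camera adjusted p = 0.0532), where their mean was −0.061 against −0.074 over all arrays. Immediate early genes had 14 of 20 members below 0, among them Fos at −0.39 ± 0.12 and Junb at −0.30 ± 0.15 (camera adjusted p = 0.0274, and adjusted p = 0.371 with an estimated correlation). Their mean of −0.075 became −0.038, −0.075 and −0.047 without wild-type arrays 2 or 3 or knockout array 1, and the call ended (adjusted p = 0.171, 0.0691 and 0.172), as it did with no filter on dim probes (mean −0.038, adjusted p = 0.0967). The mean was −0.11 both without wild-type array 1 (camera adjusted p = 0.00498) and without knockout array 3 (0.0305), where the call stayed. Fibrocyte genes of the spiral ligament and limbus had 12 of 19 members below 0, with the proteoglycans Lum at −0.26 ± 0.09 and Fmod at −0.28 ± 0.14 and the water channel Aqp1 at −0.48 ± 0.21 (camera adjusted p = 0.0481, and adjusted p = 0.694 with an estimated correlation). The fibrocyte mean of −0.073 became −0.038 and −0.073 without wild-type arrays 1 or 2, which ended the call (adjusted p = 0.173 and 0.0688), and −0.052 and −0.079 without knockout arrays 1 or 3 (adjusted p = 0.172 and 0.14). The call also ended with array weights (mean −0.019, adjusted p = 0.493). It ended with no filter on dim probes (adjusted p = 0.0967) and with the mean of a gene's probes (0.0558), both at an unchanged mean of −0.073.

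**Figure D2:**
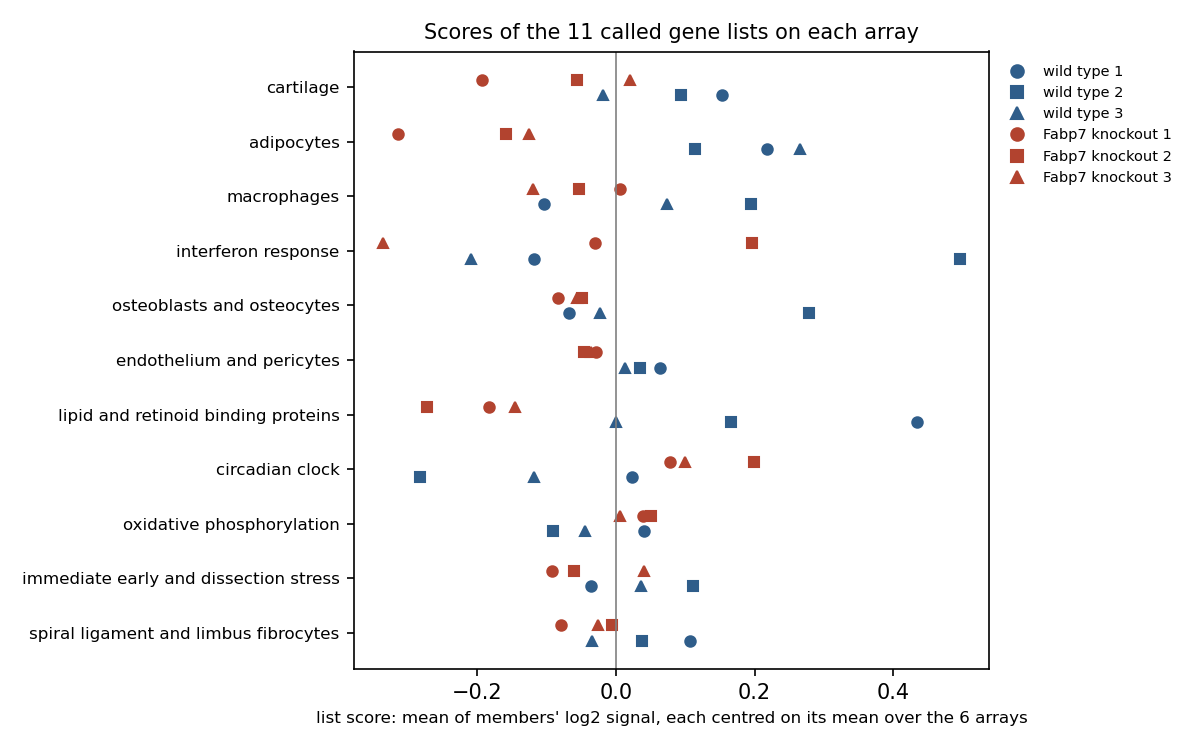
Score of each of the 11 called gene lists on each array, the mean of the members' log2 signals after each member was centred on its mean over the 6 arrays, with wild type in blue and knockout in red. The groups do not overlap for 4 lists, among them the adipocyte list, and wild-type array 2 alone holds the highest interferon score, 0.50.

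On the higher side, the clock list had 11 of 15 members above 0 and a mean of 0.25. Per2 and Per3 passed when adjusted over the list alone, as did the repressor Bhlhe40 (0.34 ± 0.09), against 0 over all genes, and the output factor Dbp was at 1.01 ± 0.29, with 0.99 by its second probe. Members that peak in the opposite phase went the other way, with Npas2 at −0.59 ± 0.18 and Arntl at −0.45 ± 0.16. The camera adjusted p was 0.0144, with an adjusted p of 0.694 with an estimated correlation. The median change of all features was 0.034, so a count of members above 0 overstates a shift upwards. Oxidative phosphorylation genes were above 0 in 26 of 30 members, among them the complex I subunit Ndufa9 at 0.14 ± 0.07. Their mean was only 0.063, with 0 members at an unadjusted p under 0.05 by limma (camera adjusted p = 0.0197, and adjusted p = 0.960 with an estimated correlation). That call ended with quantile normalization, at a mean of 0.027 (adjusted p = 0.322), and without wild-type arrays 2 or 3 or knockout array 2, at means of 0.034, 0.057 and 0.054 (adjusted p = 0.352, 0.119 and 0.145). Without wild-type array 1 the mean was 0.099.

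**Figure D3:**
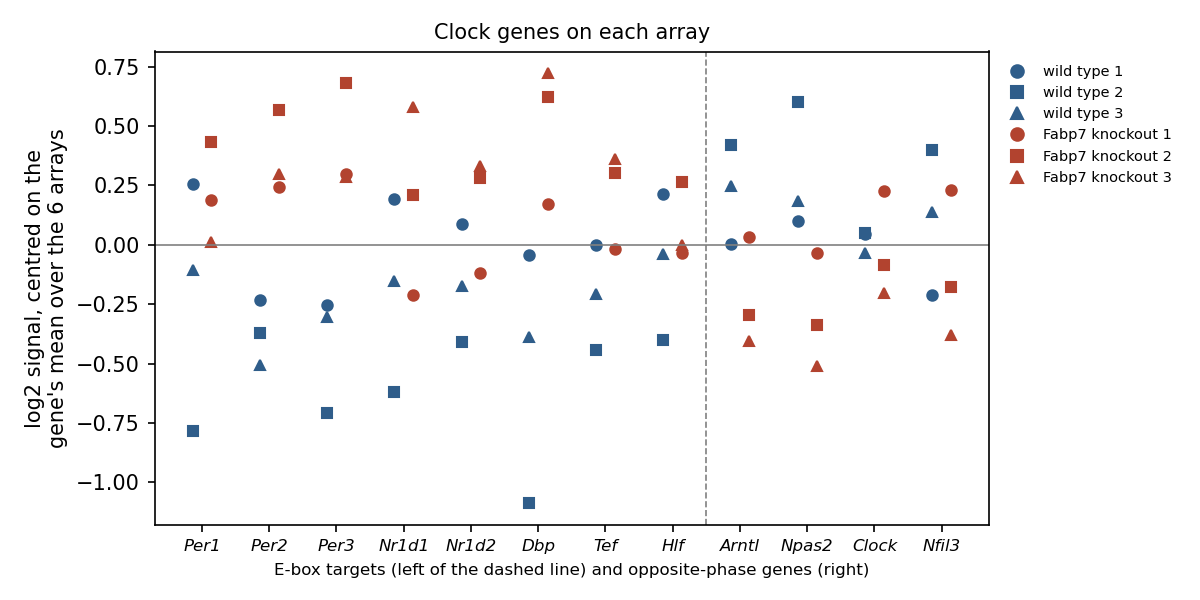
Log2 signal of 12 clock genes on each array, each gene centred on its mean over the 6 arrays, with wild type in blue and knockout in red. The 8 genes left of the dashed line had positive mean changes and the 4 to its right negative ones. The mean of the left genes minus that of the right ones was 0.04, −0.97 and −0.37 on the wild-type arrays and −0.05, 0.64 and 0.70 on the knockout arrays.

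Camera did not call the lists for the cells that hear and transmit sound, nor those for the stria vascularis and antioxidant enzymes. Hair cell genes were above 0 in 20 of 22 members, including the outer hair cell motor Slc26a5 (0.92 ± 0.25) and oncomodulin (Ocm, 0.33 ± 0.12), with a camera adjusted p of 0.0651. Their list scores were 0.15, −0.46 and 0.01 in wild type and 0.14, −0.08 and 0.24 in knockout, so that wild-type array 2 alone held the low value. Spiral ganglion neuron genes had a median change of 0.01 (adjusted p = 0.892), with 14 members above 0 and 12 below, and with tyrosine hydroxylase (Th) at 0.30 ± 0.07. Genes of Schwann cells and satellite glia had a median of 0.03 (adjusted p = 0.829) and a mean of −0.0019. Of these, 12 members lay above 0 and 7 below, with S100b at 0.26 ± 0.08. Genes of the stria vascularis, the epithelium that makes the endocochlear potential, had a median of −0.02 and a mean of 0.02 (camera adjusted p = 0.765, and adjusted p = 0.00956 by the mixed test of fry). Its member Trpm1, named above, passed when adjusted over the list alone. That rests on a probe at −0.67, while its other probes past the filter gave 1.34 and 0.92. The nuclear receptor Esrrb was at 0.34 ± 0.11, with the potassium channels Kcnq1 at 0.27 ± 0.11 and Kcnj13 at 0.22 ± 0.09. Supporting cell genes had a median of 0.03 and a mean of −0.0043, with Epyc, named above, the tectorial membrane protein Ceacam16 at −0.33 ± 0.11 and Lgr5 at −0.38 ± 0.13 (adjusted p = 0.457). Antioxidant enzymes were above 0 in 30 of 39 members, with a mean of 0.04 and 0 members at an unadjusted p under 0.05 by limma. That mean lay close to the median change of all features, 0.034. Among them Gpx4, which reduces lipid peroxides, was at 0.15 ± 0.07, and heme oxygenase 1 (Hmox1) was at −0.79 ± 0.43 (camera adjusted p = 0.180). Over the 22 lists that camera did not call, its adjusted p ranged from 0.0538 to 0.980.

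Genes that lie close to Fabp7 were compared apart, since a knockout made in one strain and bred into another can keep a stretch of the donor chromosome. In the planned count, limma called 0 of the 212 genes measured within 20 Mb. At a level chosen after this was seen, 23 were at an unadjusted p under 0.05, 13 lower and 10 higher. Hkdc1 and Pdss2, named above, were among them, as were, named after their values were seen, Scml4 at −0.52 ± 0.09, Foxo3 at −2.36 ± 0.43 and Mcm3ap at −0.36 ± 0.07 on the lower side and Arid5b at 0.44 ± 0.11, Mif at 0.23 ± 0.06 and S100b at 0.26 ± 0.08 on the higher side. The second Foxo3 probe gave a log2 change of opposite sign, 1.29. The planned list of 23 nearby genes, all measured, had 1 member at that level and a median change of 0.06 (camera adjusted p = 0.980). The share at that level was 10.8% near Fabp7 and 4.71% among the 15930 other named genes, an odds ratio of 2.46 with a 95% interval of 1.51 to 3.84 (Fisher's exact test, two-sided, p = 0.000245). Neighbouring genes are not independent, which this p does not allow for. Within 5 Mb 4 of 66 genes reached that level (odds ratio 1.28, Fisher's exact p = 0.558), and within 50 Mb 46 of 586 (odds ratio 1.74, Fisher's exact p = 0.00104). Without knockout array 3 the odds ratio over 20 Mb was 1.5 (Fisher's exact p = 0.0919), as it was with array weights (Fisher's exact p = 0.0314).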

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

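Tests on named genes alone, above the array median and with a floor at the 40th percentile, and the odds ratio near Fabp7, were chosen after the results were seen. The count of higher genes, 0, became 1 with array weights (Dupd1), 20 at an unadjusted p under 0.05 with a 2-fold change, and 0 to 2 without each array in turn. The count of lower genes, 0, became 1 with quantile normalization, with the 40th percentile passed on all 6 arrays or on all 3 of a group, with an intensity trend and robust prior, with named genes only, above the array median, with the floor and at an adjusted p under 0.10. It became 2 with array weights (Fabp7 and Slco1b2), 47 at an unadjusted p under 0.05 with a 2-fold change, and 0 to 1 without each array. Fabp7 kept its direction in all 20 alternatives, and passed in 9: at −8.35 with quantile normalization, at −8.42 with the stricter filters, the trend, named genes only or the array median, at −8.64 with array weights, at −6.57 with the floor, and once among the fits without each array, which ran from −8.95 to −8.15. Fabp7 was tested whatever the filter, and its knockout signals did not meet the filter on all 6 arrays. Stricter filters and named genes only adjusted over fewer features, and otherwise the cause was not tested. Features at an unadjusted p under 0.05, 827 higher and 723 lower, became 2125 and 1302 with array weights, 499 and 413 with named genes only and 1314 and 801 without wild-type array 1. Called lists numbered 17 with array weights, 0 with an estimated correlation, 0 by fry in one direction and 4 by its mixed test (2 of them not called by camera), and 11 to 20 without each array. The named lists kept their calls in 186 of 220 values. The interferon list reversed, to a mean of 0.077 with array weights and to 0.11 and 0.027 without wild-type array 2 or knockout array 3, with fits without each array from −0.25 to 0.11. Named genes had 467 values, since a gene that a filter left out has none. Among the other named genes, Trpm1 reversed to 0.53 with the mean of its probes, which are of opposite sign. With the replicate number as a block, limma called 0 genes, 1199 features had an unadjusted p under 0.05 (583 higher and 616 lower), and Fabp7 was at −8.42 (adjusted p = 0.0582). Camera with this block called 12 lists, without fibrocytes (mean unchanged at −0.073, adjusted p = 0.0538) and oxidative phosphorylation (mean unchanged at 0.063, adjusted p = 0.0575). The numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.13, −0.04 and −0.14, and 0 arrays correlated best with their own number. Genes near Fabp7 past the adjusted threshold stayed at 0 throughout. Normexp background correction and a slide or scan date block were not run. Without background estimates, changes of dim probes have no stated limit.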

Other observations

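Chosen after results were seen were the tests of shared variation in the lists, those of the clock limbs, and those of genes around Fabp7 at an unadjusted p, with their splits of the arrays. The list tests, the count of called genes near Fabp7 and the splits for genes and lists were planned.

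Genes of skeletal muscle, a tissue outside the cochlea, were above 0 in all 14 measured members, with Myl1 at 1.79 ± 0.95 (SE) and Mybpc1 at 0.43 ± 0.12. Their list scores were 0.34, −0.33 and −0.88 in wild type and −0.81, 2.21 and −0.54 in knockout, so that knockout array 2 held the high value (camera adjusted p = 0.0611). Blood and marrow genes also varied between pools. Erythroid scores were −0.50, 0.17 and 0.31 in wild type and 0.04, −0.02 and −0.0049 in knockout (adjusted p = 0.765), and cell cycle scores were −0.43, 0.18 and 0.18 against 0.12, −0.0088 and −0.03 (adjusted p = 0.962). Wild-type array 1 was the lowest in both.

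The probes of Ermn, an oligodendrocyte gene, differed in sign. It was at −0.75 by its brightest probe and at 0.31 by its second. For Dbp (1.01 and 0.99), Hmox1 (−0.79 and −0.84) and Cidec (−0.73 and −1.17) the probes agreed in sign.

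The 11 lists called with a preset correlation were set against shared variation between the pools. Of them, 7 had an estimated correlation between members above the preset 0.01, the highest 0.675, as pools that differ in tissue makeup whatever their genotype would give. For the adipocyte, lipid and retinoid binding, vessel and immediate early lists the estimates were −0.011, −0.051, −0.017 and −0.0049, under the preset. Their calls ended as well with an estimated correlation (camera adjusted p = 0.371 each). Correlation between members therefore does not account for the loss of these calls. With an estimated correlation, camera also takes its degrees of freedom from the arrays instead of the genes. For the adipocyte list its unadjusted p went from 5.75e-05 to 0.0133. The adjusted p-values at this setting thus do not measure correlation between members alone. The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. For lists the real split gave 11 and the highest other 20, with 6 splits at or above the real one, for features at an unadjusted p under 0.05 it gave 1550 against 2897 (3 splits), and for genes past adjustment 0 against 0 (10 splits). These counts of splits include the real one. The split with 2897 features, wild-type array 1 and knockout arrays 2 and 3 against the rest, also called 19 lists and points to a structure of the samples across genotype, so a difference by genotype in these lists stays open.

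Of the clock genes 0 passed over all genes, but all 8 E-box targets had positive mean changes (mean 0.54) and all 4 opposite-phase genes negative ones (mean −0.32, with Clock at −0.04 ± 0.12, SE), a difference between these limbs of 0.863 with a pooled SD of 0.465. Scaling of the arrays was tested by that difference, which decides nothing because a constant per array cancels in it, and then, in a test added once this was seen, by correlating the limbs across the 6 arrays, where scaling would give a value above 0: Pearson's r was −0.92 (exact permutation p = 0.0139) and Spearman's rho −0.89 (exact permutation p = 0.0333), with r at −0.86 without the 2 arrays farthest from the median. Of 10000 random pairs of gene sets matched on signal, 0% differed as much (highest 0.810), a test that ignores any correlation among clock genes. It was also chosen after the changes of these genes had been seen, so it gives no independent support. The limb difference of wild-type array 1 (0.04) exceeded that of knockout array 1 (−0.05). Of 10 splits, too few for a share under 0.05, the real one gave 0.863 and the highest other 0.925, with 2, the real one included, at or above 0.863. The split with 0.925 was wild-type array 1 and knockout arrays 2 and 3 against the rest, the one that also gave 2897 features at an unadjusted p under 0.05. The clock difference was thus largest along the structure across genotype described above. A different time of collection may account for the pattern and cannot be told apart from an effect of genotype, since 0 labels give a time of day.

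Around Fabp7, 10.8% of genes within 20 Mb reached an unadjusted p under 0.05. A window of the same width was set around each gene of the other chromosomes, and 0.0274% of these 14584 windows had as high a share (median 4.31%, highest 10.9%). The windows overlap heavily, so that percentage is not a p-value. Since some of them matched it, they argue only weakly against neighbours moving together anywhere in the genome. Of the 10 splits of the arrays, too few for a share under 0.05, the real one had an odds ratio of 2.46 and the highest other 1.37. A stretch of donor chromosome may be the source, but genes within 5 Mb reached that level at an odds ratio of 0.433 (95% interval 0.103 to 1.38) against the rest of the window, which leaves this open. Sequence variants under single probes may contribute: in 6 genes with further probes, these gave a median change of −0.0661 times that of the chosen probe, against 0.499 elsewhere, with an interval from −0.41 to 1.17 that also decides nothing. An effect of Fabp7 loss itself on these genes was not tested apart from them.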
